A study of Drosophila melanogaster with 8 samples.

How the data were processed

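P-p38 was immunoprecipitated from sonicated nuclei of wild-type Drosophila S2 cells, and the DNA was sequenced. Per the labels, cells received 10 mM H2O2 for 30 min at 25 ºC or the same volume of medium. The series describes 8 samples, of which 4 are immunoprecipitations (2 control, 2 H2O2) and 4 are inputs (2 per group). Inputs have no peak list and were not analysed here. Per the submitters' processing notes, Picard and MACS2 were used on genome build dm6, and their versions, options and background library are not given in the sources used here. Whether inputs served as that background is likewise not given, so the fold enrichment may or may not be over input.

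Each deposited list holds 1 peak per line with its interval, a score, a fold enrichment, a p-value, a q-value and a summit. The deposited score is the whole part of 10 times the -log10 p-value, which was checked and held for 17926 of 17927 peaks. The authors' fold enrichment is a linear ratio over the peak caller's background. The deposited p-value and q-value are both on the -log10 scale. The lowest -log10 p was 2.00 to 2.01 in the 4 lists, as a limit of 0.01 on p gives, and no peak was narrower than 200 bp. Because the median fold was 1.63 to 1.64 in every list and its background is unknown, folds were turned into percentiles within each list and were not compared across libraries as levels. Read depth is unknown, so Wilson 95% intervals are given only for shares of peaks or regions, and they cover counting error only.

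Analyses covered the arms 2L, 2R, 3L, 3R, 4 and X, which hold 17755 of the peaks. Peaks overlapping by at least 1 bp were merged across libraries into regions, and a region was called in a library with at least 1 peak in it. Regions were grouped as H2O2-only (both H2O2 libraries, neither control library), control-only (the converse) and all 4. Observed numbers were set beside 1000 random placements of each library's peaks on their own arms (seed 1). Gene positions came from the RefSeq table for Release 6 of the genome, with 13911 protein-coding genes on the arms. That table has no strand, so the planned promoter window became a window of 500 bp around either end of a protein-coding gene, which also takes in gene ends that are not starts. The genome sequence was not used here, so a planned test of 25 motif consensus sequences at summits was not run, and exons and introns were not separated. Centromere-proximal parts were set by eye after the lists were seen.

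The number of peaks and the shares per library were compared by an exact two-sided permutation of the group labels, for which 2 against 2 libraries give 6 arrangements and a smallest p of 0.333, so no such comparison can pass 0.05. Nothing says that replicates were separate cultures, and the permutation p-values measure only the spread between these samples. Shares of region classes were compared by two-sided Fisher's exact tests, which treat regions as independent, with Benjamini-Hochberg adjustment over 12 tests. The 21 gene lists, the tests of lists and of libraries and the alternatives were fixed before the data were examined, except for the window around either gene end, the class tests, whose proximal parts were set later, and the alternatives named as added. Of 531 symbols written in the lists 524 were matched and 7 were not, and 3 lists were given as name patterns. A gene was called in a group when both libraries had a summit within 500 bp of an end. The libraries did not need to share the end or the peak. Lists were tested by two-sided Fisher's exact tests against all other protein-coding genes, adjusted over 42 tests of both groups. Genes of H2O2-only and control-only calls were compared within each list by an exact two-sided sign test, and list members among H2O2-only genes by Fisher's exact test, each adjusted over 21 lists. The tests of lists treat genes as independent, although neighbouring genes can share a summit. They take no account of gene length or of the spread between libraries, so they are no test across cultures. All lists were tested and each has its result in the text.

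Named regions followed a rule fixed with the design: the 15 H2O2-only, 10 all-library and 5 control-only regions at gene ends with the highest value of the lowest percentile across their libraries, the 3 widest regions of all 4 libraries, and up to 4 members per list, with p38a, p38b, p38c, kay, Jra and puc reported whatever their values. For counts of 5 or fewer the members were named, except for 1 member of the p38 and JNK list that is not reported here, and other genes were chosen after their values were seen, as were the H2O2-only regions at any distance from a gene. The replicate numbers are shared between groups, but the labels do not say that they pair the libraries, so no replicate block was used in the main comparisons.

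Alternatives were a q of 1e-05 or less, lists of equal length (the 2988 peaks with the highest fold), summits within 100 bp or a reciprocal overlap of 50% as the meaning of shared, all sequences, windows of 250 and 1000 bp, a background of genes called in any library, each library left out in turn and a replicate block. A q of 0.05 or less, genes overlapped anywhere by a peak, regions without the proximal parts and proximal limits moved by 1 Mb were added after the data were seen. The scripts were tested on 20 simulated sets of 4 lists with 1500 random peaks per library. With 200 regions planted in every library, 400 H2O2-only and 300 control-only, means of 200.7, 401.8 and 305.55 were found. The planted gene list was called in 20 of 20 sets, and 0 of 840 tests of other lists passed. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.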

Results

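Phosphorylated p38 (P-p38), the active form of a stress-activated MAP kinase, was mapped on chromatin by ChIP-seq in Drosophila S2 cells, a haemocyte-like embryonic line. Cells were exposed to 10 mM H2O2 for 30 min or received medium alone, and the comparison asks where P-p38 lies on the genome with and without oxidative stress. The analysis rests on 4 lists of peaks, 1 per immunoprecipitated library, with 2 libraries per group. The 4 input samples, 2 per group, have no peak list and were not analysed here. Across the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X of dm6) the lists held 4314 and 2988 peaks in control replicates 1 and 2, and 6434 and 4019 peaks in H2O2 replicates 1 and 2. Read depth per library is not given in the sources used here, so the precision of each list is known only through its replicate. Nothing in the labels says that replicates came from separate cultures, and permutation p-values therefore measure only the spread between these samples. Fisher's exact and sign tests treat regions or genes as independent and hold no spread between libraries.

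Control lists held more wide peaks and more peaks over genes than H2O2 lists, whose peaks lay more often between genes. Median widths were 324 and 354.5 bp in control and 296 and 270 bp in H2O2. Peaks wider than 1000 bp made up 11.2% and 12.3% of the control lists and 3.05% and 2.61% of the H2O2 lists, and the widest peak reached 13392 bp in control and 6158 bp in H2O2. A summit inside a protein-coding gene was found for 88.6% ± 3.41 (SD, n = 2) of control peaks and 67.9% ± 5.13 (SD, n = 2) of H2O2 peaks. Summits within 500 bp of either end of such a gene accounted for 26.6% ± 9.68 (SD, n = 2) of control peaks and 11.2% ± 3.14 (SD, n = 2) of H2O2 peaks. In each of these measures both H2O2 libraries lay on the same side of both control libraries, which gives an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries allow. Of regions called in both H2O2 libraries 63.2% had a summit inside a protein-coding gene, close to the 66.3% of random placement. Of those called in both control libraries 90.4% did, against 66.9% by random placement. The number of peaks per library was 3651 ± 938 in control and 5226.5 ± 1708 in H2O2 (mean ± SD, n = 2 each), a ratio of 1.43 with an exact permutation p of 0.667, so it did not exceed the spread between replicates. At q of 1e-05 or less the order turned, with 931 and 767 control peaks against 624 and 306 H2O2 peaks, a ratio of 0.548.

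Libraries of the same treatment shared more regions than libraries of different treatments. Within control 30.8% of the peaks of replicate 1 overlapped a peak of replicate 2 and 46.7% the other way. Within H2O2 24.5% of the peaks of replicate 1 overlapped a peak of replicate 2 and 39.7% the other way. Between treatments the overlap ran from 8.07% to 23.7%, and random placement of the peaks on their own arms gave 2.21% to 4.91%. The Jaccard index in base pairs was 0.257 within control, 0.15 within H2O2 and 0.0534 to 0.115 between groups. Merging all peaks gave 12632 regions, of which 9634 were called in 1 library, 2246 in 2, 557 in 3 and 195 in all 4. Regions called in both libraries of one treatment and in neither of the other numbered 1587 for the split by treatment, 421 for the split by replicate number and 238 for the crossed split, against 240, 259 and 234 after random placement.

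**Figure D1:**
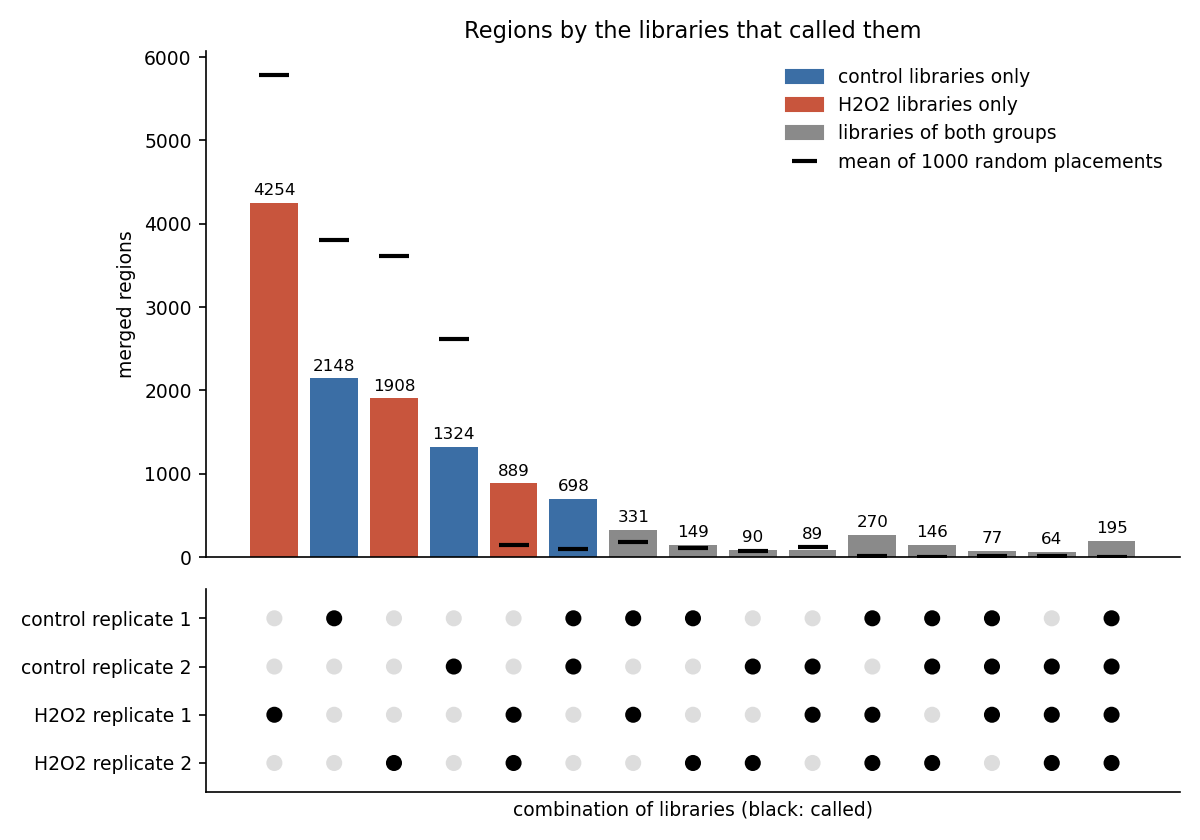
Number of merged regions (y axis) for each combination of libraries that called them (x axis, black dots mark the libraries), with bars coloured by treatment and black dashes for the mean of 1000 random placements. The 889 regions of both H2O2 libraries alone and the 698 regions of both control libraries alone stand above the 146 and 93.5 of random placement.

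Among regions called in every library, the strongest at gene ends included those over the heat shock genes Hsc70-4, Hsp83, Hsp26 and Hsp70Ab and the cytoskeletal genes chic and alphaTub84B. Hsc70-4, a constitutive Hsp70-family chaperone, carried a region of 5166 bp (3R 15242532 to 15247697) that stood at or above percentile 99.6 of the authors' fold enrichment within each of the 4 lists. The profilin gene chic had a region of 11315 bp (2L 5969798 to 5981112), and Xrp1, a bZIP transcription factor of the stress response, had one of 9623 bp (3R 18918138 to 18927760). Hsp83, which encodes the fly Hsp90, Hsp26, a small heat shock gene, Hsp70Ab, alphaTub84B, the proton pump gene Vha16-1, CG2765 and CG46460, whose region also covers the insulin-binding gene ImpL2, completed the 10 strongest, with a lowest percentile of 95.5. The 3 widest regions called in every library covered Jupiter (13397 bp), the calmodulin gene Cam (12350 bp) and chic. There were 195 regions called in every library, where random placement gave 1.89, and their median width was 1347 bp. A summit within 500 bp of a gene end was found in 25.6% of them, and 15.9% lay neither inside a protein-coding gene nor near one of its ends. Hsp70Ab belongs to a multicopy family, and reads from its copies may not be separable. The count was 57 when only summits within 100 bp were taken as shared, 85 when at least 50% of both peaks had to overlap, 44 at q of 1e-05 or less and 115 with lists of equal length.

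Regions called in both control libraries and in neither H2O2 library had their strongest members at gene ends mostly over ribosomal protein genes. The strongest at gene ends covered RpLP1 with its neighbour CG11885 (2L 419943 to 421402), RpL15 (3L 27267168 to 27269447), RpLP2 (2R 16586043 to 16587625), RpL10 (3L 23092167 to 23095565) and the cyclophilin gene Cyp1 (X 16318187 to 16320406), each at or above percentile 97.0 of both control lists. These 698 regions had a median width of 785.5 bp, and random placement gave 93.5. A summit within 500 bp of a gene end was found in 36.4% of them (95% Wilson interval 32.9 to 40.0), 2.39 times the 15.2% of random placement, and 94.1% had a summit inside a protein-coding gene. At q of 1e-05 or less 219 such regions remained and 52.5% of them lay at gene ends, while 321 were counted when only summits within 100 bp were taken as shared and 446 when at least 50% of both peaks had to overlap. With a single control library standing for its group the count was 2241 for replicate 2 and 3042 for replicate 1, and without control replicate 2 the share at gene ends was 22.1%.

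Regions called in both H2O2 libraries and in neither control library were narrower and lay away from gene ends. At gene ends the strongest were at alphaTry, a trypsin-family protease gene (2R 11344433 to 11344759, lowest percentile 89.1), the homeobox gene HHEX (3R 21075435 to 21077302, 85.1) with dmrt93B in the same region, CG13720 (84.9), the cuticle protein gene Lcp65Ag1 (81.3) and DIP-delta, an immunoglobulin-superfamily gene (80.2). ACXC, Oseg2, h-cup, Shawn, CG32488, the cuticle gene Acp65Aa, CG34232, CG14340, the carbonic anhydrase gene CAH15 and CG42700 completed the 15 strongest, at 61.5 to 73.2. The authors' fold enrichment at these 15 regions ran no higher than 2.37 in H2O2 replicate 1 and 2.30 in H2O2 replicate 2. In all there were 889 such regions against 146 by random placement, with a median width of 456 bp. Only 9.11% (7.39 to 11.2) had a summit within 500 bp of a gene end, 0.597 times the random share of 15.3%, and 38.2% lay neither inside a protein-coding gene nor near one of its ends, against 3.15% of control-only regions. A summit inside a protein-coding gene was found in 59.7% of the H2O2-only regions, against 66.2% by random placement. Fisher's exact test, which treats regions as independent, separated H2O2-only from control-only regions in the share at gene ends (adjusted p = 9.72e-40) and from the regions of all 4 libraries (adjusted p = 7.7e-09). This set was the most sensitive to the threshold: 44 regions were left at q of 1e-05 or less, of which 2.27% lay at gene ends, and 406 with lists of equal length. H2O2 replicate 1 alone gave 5204 and H2O2 replicate 2 alone 2889.

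The H2O2-only regions gathered in the gene-poor parts of the arms next to the centromeres. Of these regions 33.0% (29.9 to 36.1) lay in the centromere-proximal parts, limits set after the lists were seen at 22 Mb of 2L, 5.7 Mb of 2R, 23 Mb of 3L, 4.2 Mb of 3R and 22 Mb of X, against 4.01% (2.79 to 5.74) of control-only regions and 23.1% (17.7 to 29.5) of the regions of all 4 libraries (Fisher's exact test of H2O2-only against control-only regions, adjusted p = 5.4e-52). Random placement gave 15.8% for H2O2-only and 14.4% for control-only regions. The 3 strongest at any distance from a gene were a 234 bp region on 2R (3376239 to 3376472), 11922 bp from the nearest gene end, a 223 bp region on 3R (3767688 to 3767910) and a 391 bp region on 3R (211247 to 211637), 355658 bp from the nearest gene end. On the X chromosome lay 9.18% and 9.34% of control peaks and 3.45% and 4.48% of H2O2 peaks, and 11.7% of control-only against 4.05% of H2O2-only regions (Fisher's exact test, adjusted p = 1.24e-08). Neither share was separated from the 6.67% of regions of all 4 libraries on X (Fisher's exact test, adjusted p = 0.126 for H2O2-only and 0.0525 for control-only regions). Among regions called in 1 library, the proximal share was 28.1% in H2O2 replicate 1 and 10.6% in H2O2 replicate 2, against 16% and 15.2% by random placement, so replicate 1 carried most of the unshared proximal peaks. Without H2O2 replicate 1, where H2O2 replicate 2 alone makes the call, the proximal share of H2O2-only regions was 18.4%. At q of 1e-05 or less the proximal share was 79.5%. With the limits moved by 1 Mb, an alternative added after the data were seen, 34.6% of H2O2-only and 11.2% of control-only regions lay in these parts.

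**Figure D2:**
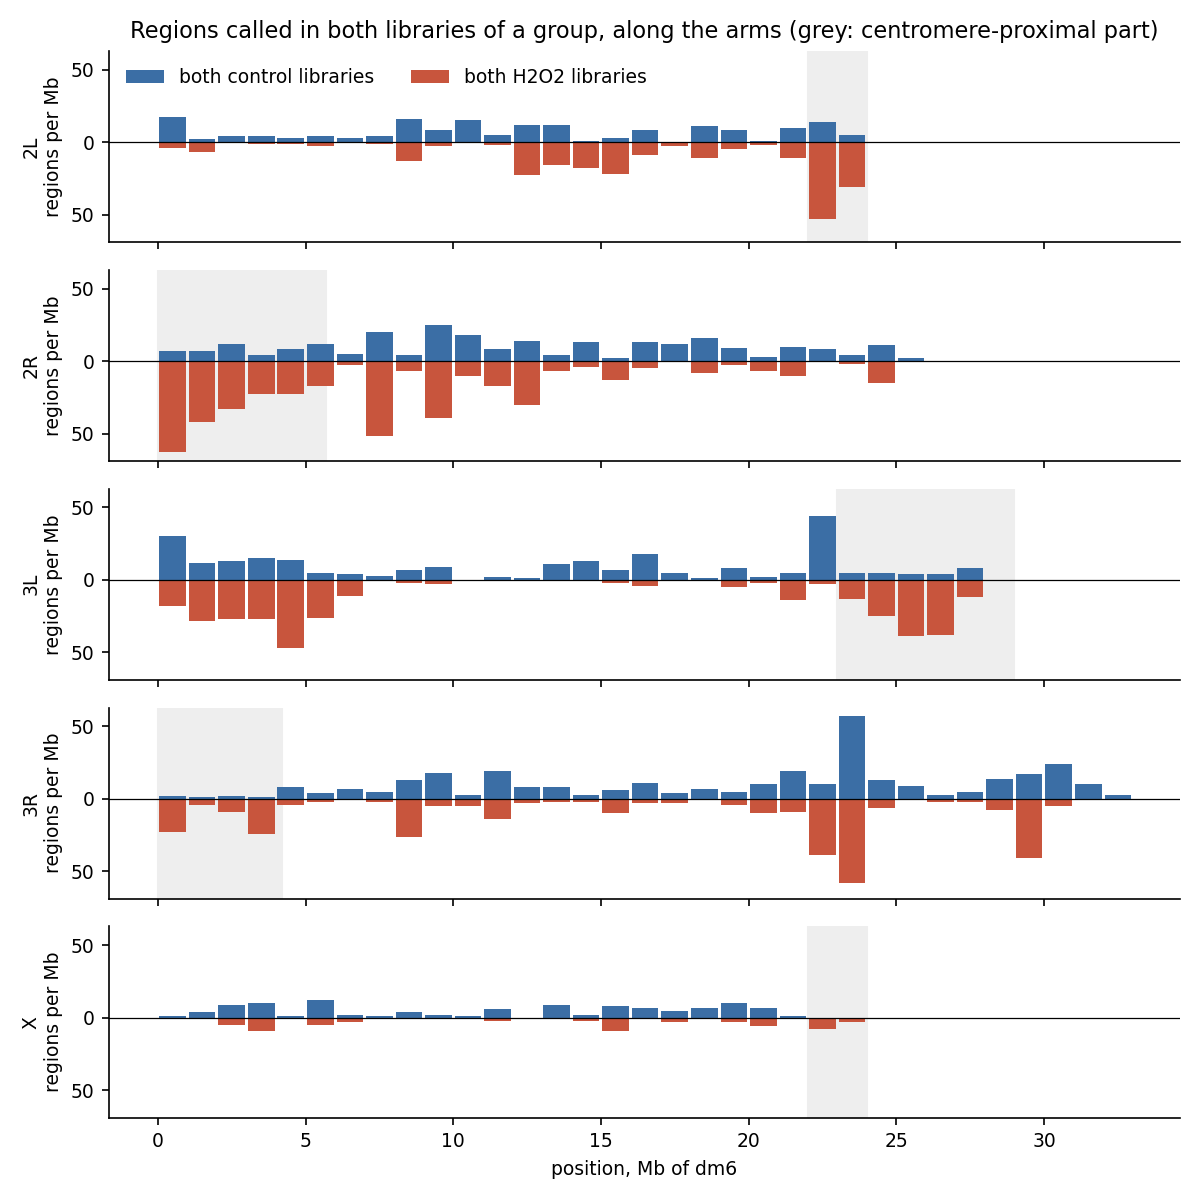
Regions called in both libraries of a group per Mb (y axis, control upward, H2O2 downward) along 5 chromosome arms (x axis, Mb of dm6), with the centromere-proximal parts shaded grey. From 0 to 1 Mb of 2R 63 H2O2 regions stood against 7 control regions, and between 22 and 23 Mb of 3L 44 control regions stood against 3 H2O2 regions.

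Ribosomal protein genes formed the largest group at control gene ends and were nearly lost from the H2O2 lists. Of 92 such genes, 63 (68.5%) had a summit within 500 bp of an end in both control libraries, against 3.05% of other protein-coding genes (Fisher's exact test, odds ratio 69.0, adjusted p = 3.11e-69). In both H2O2 libraries only RpL3 and RpL10Aa were called (2.17%, exact test, adjusted p = 0.739). Control-only calls covered 60 genes, with RpL41, RpLP1, RpL4 and RpL15 the strongest, and H2O2-only calls covered RpL10Aa alone. The exact two-sided sign test over these 61 genes gave an adjusted p of 1.13e-15, and the split differed from that of other genes, 303 control-only and 115 H2O2-only (Fisher's exact test, adjusted p = 1.15e-05). Summits within 500 bp of protein-coding gene ends were found at 485 genes in both control libraries and at 202 genes in both H2O2 libraries, 51 of them in every library. Within 250 bp of an end, 24 of the 92 ribosomal protein genes were called in both control libraries and 1 in both H2O2 libraries. In both control libraries peaks covered at least 50% of the body of 59 ribosomal protein genes, so the signal was not confined to gene ends.

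Heat shock and chaperone genes were called in both groups. Of 27 genes on this list, 13 were called in both control libraries (48.1%, Fisher's exact test, adjusted p = 2.59e-11) and 10 in both H2O2 libraries (37.0%, adjusted p = 3.18e-11), 9 of them in every library. The shared genes were the chaperones Hsc70-4 and Hsp110, the co-chaperone DnaJ-1, the small heat shock genes Hsp23, Hsp26 and Hsp27, and the near-identical copies Hsp70Aa, Hsp70Ab and Hsp70Ba, whose reads may not be separable. Hsp68 was called in both H2O2 libraries and 1 control library, and Droj2 in the control libraries alone. Hsp83 had a summit within 500 bp of an end in 1 H2O2 library and 0 control libraries, and within 1000 bp the share of H2O2 libraries minus that of control libraries was -0.5. Yet peaks covered Hsp83 over 97.0% and 99.4% in control and 94.4% and 98.1% in H2O2. Hsp68 was covered over 83.55% and 100% in control and 85.6% and 98.0% in H2O2. For these genes the calls thus differed by where the summit lay, since every library had peaks over them. Hsp26 stood at or above percentile 99.7 of both control lists and 96.5 of both H2O2 lists. Within 250 bp of a gene end only 5 and 3 of these genes were called in control and H2O2.

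**Figure D3:**
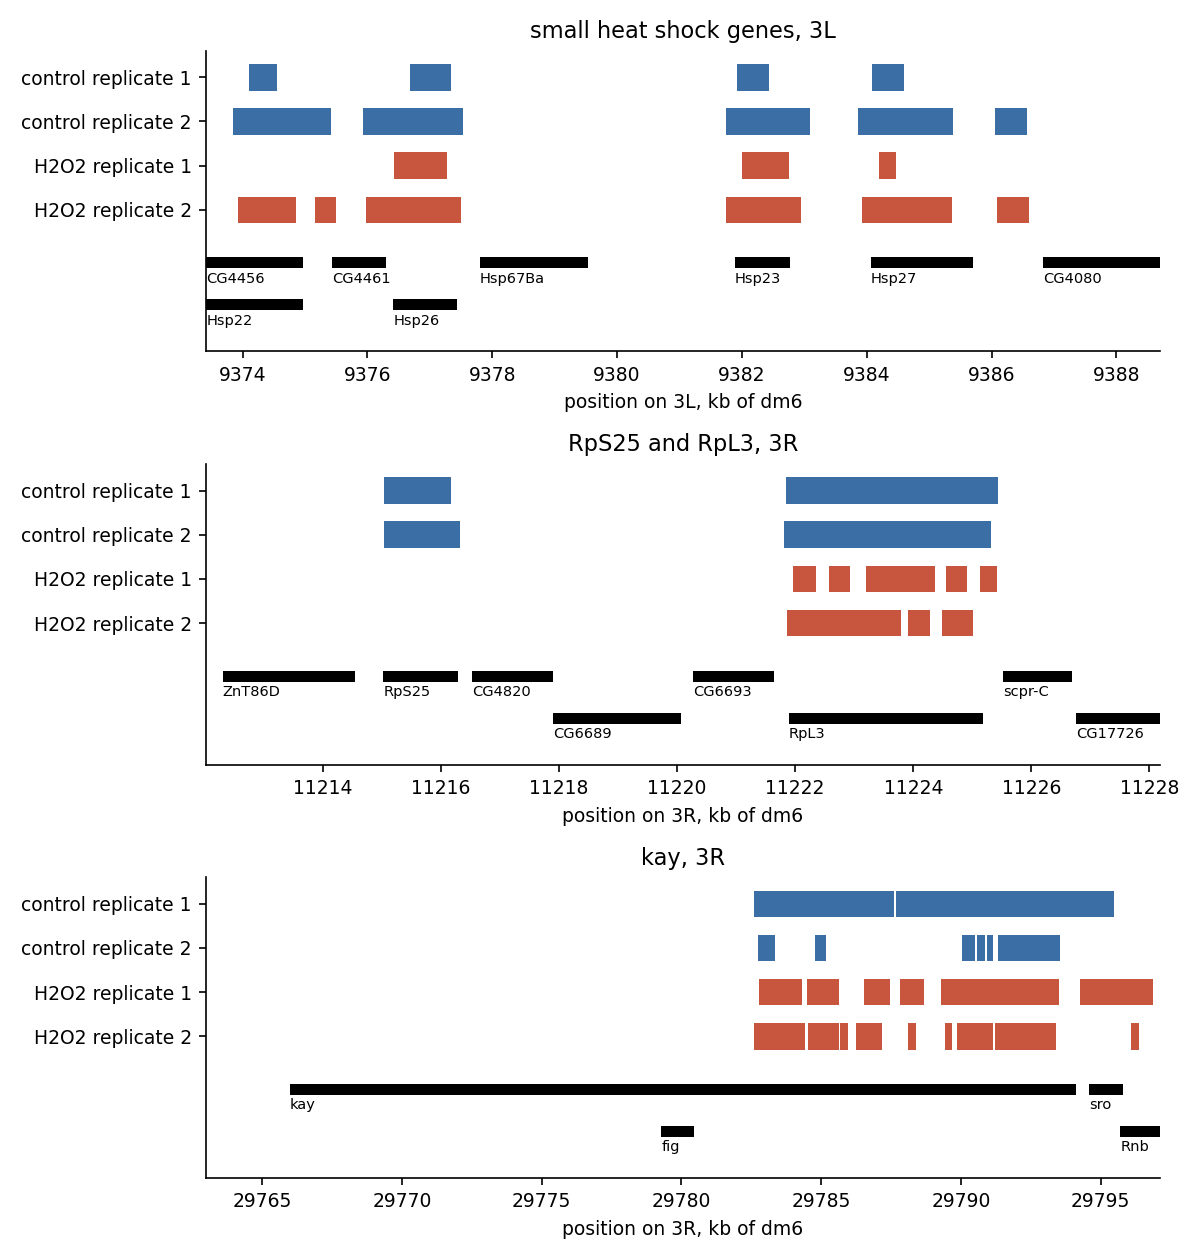
Peaks of each library (horizontal bars, blue control, red H2O2) over 3 loci, drawn to scale along the chromosome (x axis, kb of dm6) with protein-coding genes in black below. Hsp26, Hsp23 and Hsp27 carry peaks in every library, RpS25 carries peaks in the control libraries alone, RpL3 in every library, and kay in every library.

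Stress-response, cytoskeleton and housekeeping, and metabolic lists had more genes called in control than in H2O2, a difference that passed the sign test for none of them. Protein-coding genes as a whole leaned the same way, with 363 control-only and 116 H2O2-only. None of these lists differed from the split of other genes (Fisher's exact test, lowest unadjusted p = 0.204). Antioxidant and glutathione genes numbered 9 of 51 in control (Fisher's exact test here and for the lists that follow, adjusted p = 4.08e-04) and 5 in H2O2 (adjusted p = 0.00392), the latter being the glutathione transferases GstE6, GstE7 and GstE8, the pentose phosphate enzyme gene Pgd and the thioredoxin Trx2. GstE7 and GstE8 had the same percentiles in H2O2 replicates 1 and 2 (10.3 and 98.4), so the same summits may call both genes. For the unfolded protein list the counts were 10 of 24 in control (exact test, adjusted p = 3.21e-08), among them Pdi, Xbp1, Calr and crc, and 2 in H2O2, Thor and Gp93 (adjusted p = 0.132). The Xbp1 call turned with the distance: 2 control libraries and 1 H2O2 library had a summit within 500 bp, but within 250 bp the share of H2O2 libraries exceeded that of control libraries by 0.5. The cytoskeleton and housekeeping list had 10 of 28 in control (exact test, adjusted p = 1.52e-07), among them alphaTub84B, tsr, betaTub56D and eEF2, and 4 in H2O2 (betaTub56D, Ubi-p63E, chic and tsr, adjusted p = 0.00353). Among early response genes 7 of 31 were called in control (exact test, adjusted p = 4.57e-04), with Thor, Myc, puc and crol the strongest, and 3 in H2O2 (Thor, scyl and Xrp1, adjusted p = 0.0352). By the same exact test, control calls also exceeded other genes for insulin and TOR signalling (5 of 24, Thor, Pi3K92E, Lk6, S6k and Pdk1, adjusted p = 0.00520), haemocyte markers (5 of 30, zfh1, srp, Hml, ush and LanA, adjusted p = 0.0133), oxidative phosphorylation (8 of 91, Cyt-c-p, Cyt-c-d, ATPsynC and ND-ACP the strongest, adjusted p = 0.0452) and the p38 and JNK list (4 of 28, adjusted p = 0.0462). In H2O2 these 4 lists had 1, 0, 2 and 0 genes, with Thor for insulin signalling and the copies ND-51L2 and COX6AL for oxidative phosphorylation. The control calls of ribosomal proteins, heat shock genes, the unfolded protein list and the cytoskeleton and housekeeping list, and the H2O2 call of heat shock genes, passed in every alternative in which lists were tested. Every other call ended in at least 1 of them, with a highest adjusted p by Fisher's exact test in control of 0.086 for antioxidant genes, 0.963 for haemocyte markers, 0.956 for the p38 and JNK list and 1.0 for early response, insulin and oxidative phosphorylation genes, and in H2O2 of 0.3 for cytoskeleton and housekeeping, 0.647 for antioxidant and 1.0 for early response genes.

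Several programmes showed no call beyond other genes within 500 bp of a gene end in either group when both libraries had to share it. Immune genes (37), JAK/STAT and Turandot genes (17), autophagy genes (25), the ecdysone response (21) and muscle genes (27) had 0 genes called in both libraries of either group. Proteasome genes had 2 of 48 in control (Prosalpha2 and Prosbeta6) and Prosalpha6T in H2O2, glycolysis had Pgk and Pdhb in control, and DNA damage genes had Xrp1 and Diap1 in control and Xrp1 in H2O2. Neuronal genes had Syx1A and germline genes had del and rhi in control, and Polycomb-regulated genes had pnr in control and eve in H2O2. The neuronal, muscle and germline lists, which stand for programmes foreign to haemocytes, thus had 3 of 84 genes called in both control libraries (3.57%). Of all protein-coding genes outside the ribosomal protein list 3.05% were called there. With control replicate 1 alone, immune genes (8 of 37, exact test, adjusted p = 0.0195) and proteasome genes (10 of 48, adjusted p = 0.0105) passed in control, and with control replicate 2 alone glycolysis did (6 of 15, adjusted p = 0.00398). Within 1000 bp of a gene end proteasome and glycolysis genes also passed in control (exact test, adjusted p = 0.0436 and 0.045). When a peak anywhere over a gene counted (added), neuronal and muscle genes passed in H2O2 by Fisher's exact test. When the groups were compared directly by the exact sign test, only ribosomal proteins passed, and without control replicate 1 there were 4 such lists. Cytoskeleton and housekeeping genes followed with 7 control-only and 0 H2O2-only genes (exact test, adjusted p = 0.164), and the unfolded protein list with 6 and 0 (adjusted p = 0.219). No list stood out among the 116 H2O2-only genes, with 0 of 21 at an adjusted p under 0.05 and 0 at an unadjusted p under 0.05 by Fisher's exact test, whose lowest unadjusted p was 0.165.

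**Figure D4:**
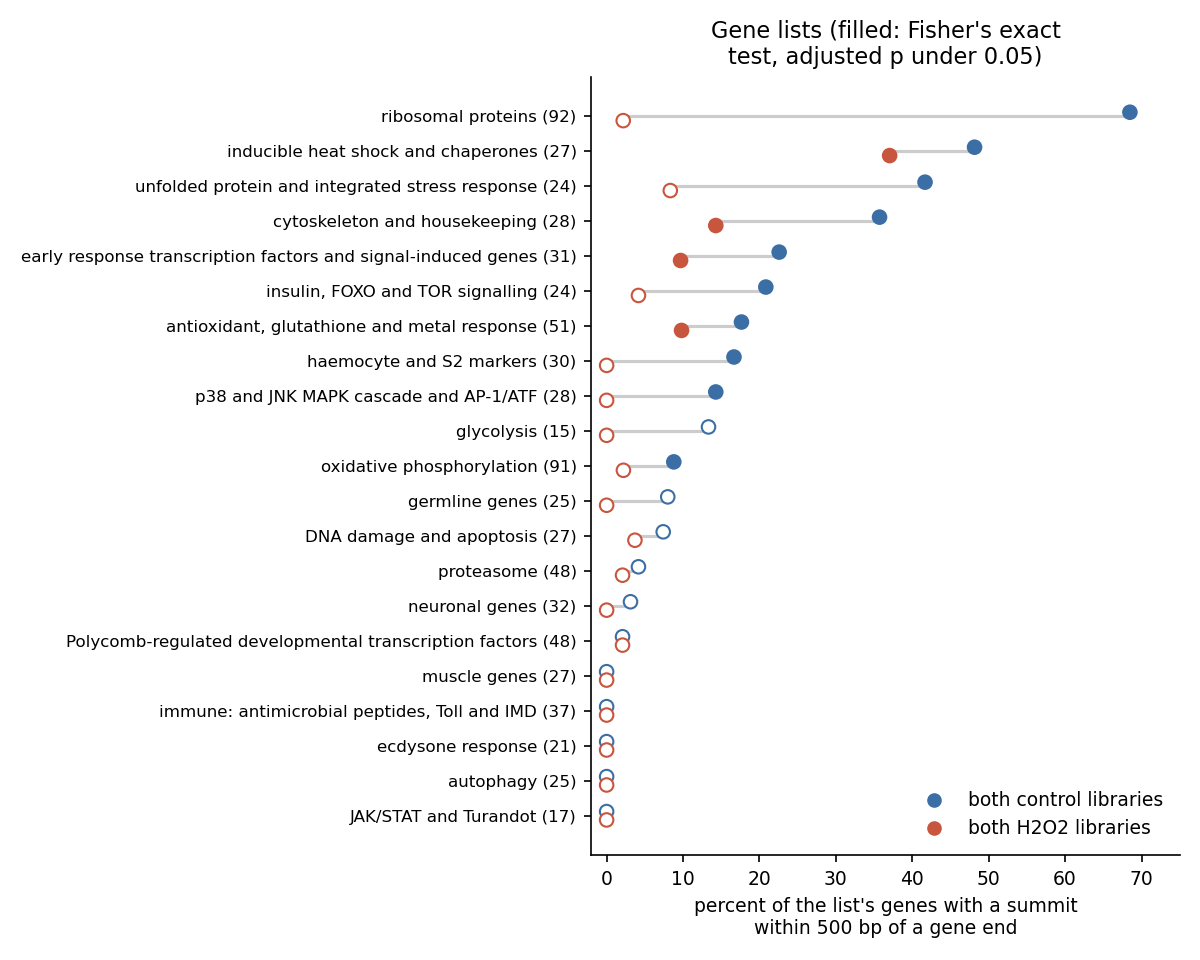
Percent of each list's genes (x axis) with a summit within 500 bp of a gene end in both control libraries (blue) or both H2O2 libraries (red), for 21 lists (y axis, number of genes in brackets), filled where the adjusted p passed 0.05. Ribosomal proteins fall from 68.5% to 2.17%, and heat shock genes stand at 48.1% and 37.0%.

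At genes of the p38 and JNK cascade itself most calls came from control libraries, as they did over all protein-coding genes. Of all protein-coding genes 485 were called in both control libraries and 202 in both H2O2 libraries. Jra, the fly Jun, had a summit near an end in both control libraries (percentiles 98.6 and 6.71) and in neither H2O2 library. The phosphatase gene puc, induced by JNK, had one in both control libraries and in H2O2 replicate 2 (percentile 97.1). The control calls of puc rested on opposite ends of the gene. The peak of control replicate 1 lay at 8122057 to 8122395 of 3R (percentile 62.7), that of control replicate 2 at 8105332 to 8106040 (87.4). Control replicate 1 also had a 9052 bp peak starting at 8105346. The Jra peak of control replicate 1 reached 10099365 of 2R, past the gene's end at 10098556. RpLP0-like, of the ribosomal protein list, had the same percentile in that library, so the same summit may call both genes. The phosphatase gene MKP-4 was called in both control libraries and in neither H2O2 library. The kinase gene p38a had a peak in control replicate 1 alone, and p38b and p38c had none in any library. The AP-1 gene kay, the fly Fos, had no summit within 500 bp of an end, but peaks lay over part of it in every library, from 29782605 of 3R onward, the widest measuring 7812 bp and 2188 bp in control and 4227 bp and 2189 bp in H2O2. For the 28 genes of this list the sign test gave 3 control-only and 0 H2O2-only genes (exact p = 0.25, adjusted p = 0.75), which did not pass the threshold. Its control call also ended at q of 0.05 or less, an alternative added after the data were seen (exact test, adjusted p = 0.163), with summits within 100 bp (adjusted p = 0.253) and with a window of 1000 bp (adjusted p = 0.101).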

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

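The test by random placement within the proximal parts was planned before its result was seen, and all other tests in this part were chosen only after the results were seen. Peaks on sequences outside the 6 arms, which only the alternative of all sequences counts, drew attention because they were more numerous in the H2O2 libraries. Their mean was 67.5 in H2O2 (SD 47.4, n = 2) and 18.5 in control (SD 14.8, n = 2). The libraries held 29 and 8 such peaks in control and 101 and 34 in H2O2, of which 2 in H2O2 replicate 1 lay on Y and the others on unplaced sequences. The exact two-sided permutation p was 0.333, the smallest this design allows.

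Ribosomal protein genes were called in control but not in H2O2. Of the 63 genes called in both control libraries only 3 kept a call in at least 1 H2O2 library, against 18 to 38 in 1000 draws of other control genes matched for percentile, which argues against a general loss of enrichment in the H2O2 libraries as the whole cause. Heat shock genes kept 12 of 13 (two-sided Fisher's exact p = 1.82e-10 against ribosomal protein genes). Non-specific signal over highly transcribed genes cannot be told apart from binding, because transcription was not measured here. Of genes from the neuronal, muscle and germline lists 3.57% were called in control, against 68.5% of ribosomal protein genes, as both would give. That 3.57% was no lower than the 3.05% of protein-coding genes outside the ribosomal protein list, so these lists were not depleted. Whether their genes are silent in these cells was not measured. A change of P-p38 or of transcription at these genes after H2O2 stays among the open explanations and might be separated by libraries from cells without p38.

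H2O2-only regions gathered in the centromere-proximal parts. Of these regions 293 lay there, where 1000 placements within those parts gave a mean of 56.2 and at most 80. This argues against chance overlap of peaks spread evenly over those parts. Placement could use every base, and whether peaks can be called on all of this sequence is not known here. Chance overlap of peaks crowded into fewer bases was therefore not tested. Control-only regions there also exceeded placement (28 against a mean of 6.4 and at most 15), so this excess is not particular to H2O2. A fixed property of the proximal sequence acting alike in every library is argued against as the whole cause by the shares of peaks there, which were 29.3% and 18.8% in H2O2 and 12.3% and 9.94% in control, a mean difference of 12.9 percentage points, although 23.1% of the regions of all 4 libraries lay there (1.53 times random placement) and a part common to the libraries may remain. The excess may still rest on background that differs between libraries. Without H2O2 replicate 1 the share of H2O2-only regions there was 18.4% in place of 33.0%. A single library then makes the call and 2889 regions replace 889, so this fall cannot decide about background. A response of these parts to H2O2 also stays open, and neither was tested apart from the other.

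A lower share of H2O2 peaks lay on X. Fewer peaks at gene ends in H2O2 could not account for all of it, because away from gene ends the share of peaks on X was still lower in H2O2 by 3.45 percentage points on average. Added peaks in the proximal parts of the autosomes could not either, because without those parts the difference was 5.77 percentage points. Both tests argue against these explanations as the whole cause, with 2 libraries per group and every library on its group's side. A response of X to H2O2 remains a hypothesis beside a difference between library preparations, which was not tested.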

How the results depend on the processing

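Settings named as added, and the limits of the proximal parts, were chosen only after the results were seen. Of 119 alternatives of the comparisons 77 stayed within a tolerance of the main value, 41 moved beyond it and 1 reversed. For the ratio of peaks the tolerance was an SD of 0.507, for shares the Wilson interval and for counts a set factor. The 889 H2O2-only regions thus counted as kept at 629 (q of 0.05 or less, added). So did the peak ratio of 1.43 at 1.10 without H2O2 replicate 1. Of 860 alternatives for 86 named genes 667 were equal, 191 moved and 2 reversed. Ribosomal proteins kept their excess of control-only genes by the sign test in every setting in which lists were tested, which leaves out all sequences and the overlap of 50 percent. At q of 1e-05 or less the ratio of peaks, H2O2 over control, turned from 1.43 to 0.548, with 44 regions in all 4 libraries, 44 H2O2-only and 219 control-only, 2.27% and 52.5% of the latter pair at gene ends, and 2 lists called in H2O2 and 5 in control. Lists of equal length gave 406 H2O2-only regions, 7.14% of them at gene ends, 115 regions in all 4 libraries and 2 lists in H2O2. Summits within 100 bp gave 555 H2O2-only, 321 control-only (32.7% at gene ends) and 57 regions in all 4 libraries, with 2 lists in H2O2 and 5 in control, and an overlap of 50 percent of both peaks gave 568, 446 and 85 regions. Within 250 bp of a gene end the shares were 3.82% of H2O2-only and 21.1% of control-only regions, and within 1000 bp 18.4% and 50%, since the window itself is narrower or wider. A background of genes called in any library left 1 list in H2O2 and 6 in control, with fewer genes to compare against. Genes overlapped by a peak (added) gave 7 lists in H2O2, and without the proximal parts (added) 13.3% of H2O2-only regions lay at gene ends. With the replicate block, regions called in H2O2 and not in the control library of the same number summed to 8512, the converse to 5329, and 12 lists passed the exact sign test. The p38 and JNK list was among them (exact test, adjusted p = 0.0041). A single library then makes a call, and a gene can count in both pairs. The labels give only a shared number, although peak names also carry codes that end alike in the libraries of one number and whose meaning is not given in the sources used here. The difference between replicates 1 and 2 correlated between the groups at -0.0143 over all regions and 0.184 over regions called in 2 or more libraries. The split by number gave 421 regions against 259 at random. The named genes Xbp1 within 250 bp of a gene end and Hsp83 within 1000 bp had differences in the share of libraries called, H2O2 minus control, of 0.5 and -0.5 in place of -0.5 and 0.5. Leave-one-out values ran from 953 to 5204 for H2O2-only regions, 779 to 3042 for control-only, and 271 to 467 for all libraries. They were 1.46 to 3.58 for replicate overlap within over between groups, 8.51% to 12.1% and 22.1% to 37.0% for the shares of H2O2-only and control-only regions at gene ends, 18.4% to 34.9% and 3.55% to 6.78% for their shares in the proximal parts, and 1 to 4 for lists passing the sign test, where a group then needs only 1 library. The proximal shares of H2O2-only and control-only regions were 79.5% and 3.65% at q of 1e-05 or less. With limits moved by 1 Mb (added) they were 34.6% and 11.2%. Apart from the window, background, block and leave-one-out settings, the cause was not tested. The motif test and its alternatives were not run, and lists of equal length cannot give a ratio of list lengths. Read depth is unknown, and its effect on these lists could not be measured.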

Other observations

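All tests in this part were chosen only after the results were seen, and genes were picked by their values. More protein-coding genes had at least 50% of their body covered by peaks in control than in H2O2. Such coverage was found at 162 genes in both control libraries and at 38 in both H2O2 libraries, 25 of them in every library. Ribosomal protein genes made up 59 of the control genes and 1 of the H2O2 genes, and heat shock genes 11 and 8. Thor, which encodes a translation repressor, was covered over 94.8% and 84.4% in control and 90.4% and 99.0% in H2O2, and the actin gene Act5C over 95.4% and 87.7% in control and 98.4% and 87.2% in H2O2. E(spl)mbeta-HLH, a Notch target, was covered over 100% and 95.6% in control and 86.8% and 100% in H2O2. CG13227, CG34232 and the odorant-binding protein gene Obp99d were covered over at least 50% in both H2O2 libraries with no control peak. Among snoRNA genes, 96 of 269 were overlapped by a peak in both control libraries and 3 in both H2O2 libraries, with 82 control-only and 0 H2O2-only (exact two-sided sign test, adjusted p = 3.73e-24 over 9 gene types). Protein-coding genes leaned to control too, with 503 control-only and 326 H2O2-only (exact test, adjusted p = 3.82e-09), and snoRNA genes of one host can share a peak, so that they are not independent. Of 74 snoRNA genes inside ribosomal protein genes, 55 were overlapped in both control libraries, against 41 of 195 others. Of 290 tRNA and 98 rRNA genes on the arms 0 were overlapped in both libraries of either group.

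Some long genes carried many separate summits in 1 group. Each peak has 1 summit, so these counts also depend on how signal was split into peaks. Over puc, control replicate 1 had a peak of 9052 bp where H2O2 replicate 2 had several narrower ones. The length covered by peaks was not compared for the genes named next. Ten-m, a teneurin gene of 115 kb, had 61 and 91 summits in control and 5 and 11 in H2O2. Summits in the ETS factor gene pnt numbered 34 and 26 in control and 0 and 3 in H2O2, those in Frl 14 and 15 against 0 and 0, and those in the GATA cofactor gene ush 15 and 17 against 5 and 4. The adhesion gene Con had 4 and 2 in control and 76 and 23 in H2O2, SKIP had 2 and 4 against 86 and 21, and CG45263 had 1 and 1 against 29 and 15. On 3R the windows from 23.4 to 23.5 Mb and from 23.5 to 23.6 Mb held 57 and 72 summits in H2O2 replicate 1, 21 and 23 in H2O2 replicate 2 and 5 or fewer in each control library, whereas the window from 23.3 to 23.4 Mb held 39 and 26 in control and 9 and 10 in H2O2. When a gene counted as called wherever a peak overlapped it, neuronal genes numbered 10 of 32 in H2O2 (two-sided Fisher's exact test, adjusted p = 4.44e-05) and 4 in control (adjusted p = 0.433), and the difference between the groups did not pass the exact two-sided sign test (5 H2O2-only and 1 control-only genes, adjusted p = 0.656). In this setting 7 lists passed in H2O2, among them haemocyte markers (8 of 30, exact test, adjusted p = 8.3e-04) and muscle genes (6 of 27, exact test, adjusted p = 0.011), and the counts take no account of gene length.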
